A study of Arabidopsis thaliana with 12 samples.

How the data were processed

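Gene expression was measured in whole Arabidopsis thaliana plants of the Col-0 ecotype that had grown for 7 days in shaken liquid Murashige and Skoog medium at 21 °C under constant light. L-AOPP is an aminooxy analogue of phenylalanine, used by the submitters as an inhibitor of auxin biosynthesis and also known as an inhibitor of phenylalanine ammonia-lyase. IAA is the main natural auxin of plants, and IPyA (indole-3-pyruvic acid) is its precursor, made by the TAA1 family of aminotransferases and turned into IAA by the YUC flavin monooxygenases. The 12 arrays form 4 groups of 3, each sample's group being given by its title. Mock plants received the solvent DMSO, L-AOPP plants received 50 µM of the inhibitor for 3 h, and the remaining groups received the inhibitor and then, 1 h later, either 1 µM IAA or IPyA, which leaves 2 h of exposure to IAA or IPyA. The dose of IPyA is not settled: the sample descriptions and the series design give 100 µM, and the treatment protocol gives 0.1 µM, a 1000-fold difference. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

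Per the labels, total RNA was turned into biotin-labelled cRNA, so each array carries 1 sample in 1 colour. The deposited values are linear signal intensities per probe set, made with MAS5 per the submitters' processing notes. The MAS5 version and the scaling step are not given in the sources used here. The values themselves show the scaling, since the mean signal of every array, after leaving out 2% of probe sets at each end, is 500.0. Scanner images and detection calls were not used here. Of 22810 probe sets, 64 are AFFX controls. In the platform annotation used for names, 13513 of the other probe sets are paired with 1 gene, 503 with several genes and 8730 are not listed, so these last are unnamed here. A locus in the reference gene table was found for 13436 probe sets. Probe sets with several genes were counted and not named.

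The log2 of the deposited signal, with values under 0.05 raised to 0.05, was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, and eBayes with an intensity trend) over all 12 arrays, because the groups share tissue, platform and protocol and have few arrays each. Control probe sets were left out, as were 6824 dim probe sets whose mean log2 signal lay at or below the 30th percentile (a signal of 47.4), which left 15922. A probe set was called when its Benjamini-Hochberg adjusted p within the comparison was under 0.05, with no minimum fold, and the test was two-sided. Of the tested probe sets, 8708 have 1 gene, 317 have several and 6897 are unlisted. Signals are given as mean ± SD of 3 arrays, and changes on the log2 scale with the standard error (SE) of this fit or its 95% interval.

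The titles number the replicates 1 to 3 in every group without saying what a number stands for. Whether the numbers pair the arrays was checked before the calls of any fits were compared, from the deviations of each array from its group mean. The 18 correlations between arrays with the same number lay between 0.501 and 0.685, the 36 between arrays with different numbers lay between -0.582 and 0.123, and all 12 arrays were closest to an array with their own number. Of the variance between arrays, 23.4% went with the group, 53.3% with the replicate number and 23.3% with neither. The numbers were therefore taken to pair the arrays. The fit without pairing, fixed in advance, remains the reference, and the paired fit, which adds the replicate number as a block, is given beside a result where it changes a call or moves a count of calls by more than 1.5 times.

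Before the data were examined, 25 gene lists, the rule for named genes, the comparisons and most alternatives had been fixed. The lists cover the GH3 genes, the Aux/IAA genes, the SAUR genes, other early auxin genes, auxin synthesis, auxin transport and perception, tryptophan synthesis, phenylpropanoid and lignin synthesis, flavonoids, detoxification, cell wall loosening, ethylene, cytokinin, jasmonate, salicylate, brassinosteroid and gibberellin synthesis, abscisic acid and cold, touch and wounding, glucosinolates, the cell cycle, shoot photosynthesis, root hairs, other root markers, the clock and reference genes. Only 61 of their 462 members have a named probe set, and 51 of these were tested. The 5 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, 1 probe set (the brightest) per gene, adjusted over the lists of a comparison. Another 15 lists had 1 to 4 tested members and were read gene by gene, and 5 had 0. The rule names the 10 largest rises and falls of the comparisons of L-AOPP with mock, of IAA with L-AOPP and of IPyA with L-AOPP, the 5 largest of the others, up to 4 called members of each list with a call, and 17 genes in any case. The largest rises and falls were taken only from called probe sets with 1 gene and no overlap between the arrays of the groups compared. Their shared direction in all pairs of arrays therefore follows from the rule. Of those 17, only IAA29, GH3.3, GH3.5 (WES1 in the annotation) and LBD16 have a tested named probe set. TAA1, TAR2, YUC8, IAA19, IAA5, SAUR15, ACS4, PAL1, PAL2, TT4, ARR5, ERF1 and RBCS1A have none and are not analysed here.

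After the data were seen, the same naming rule was applied to the calls of the paired fit, and further lists were built by rule: plastid-encoded genes, mitochondrion-encoded genes, the early auxin lists joined, and every group of at least 8 tested genes sharing the letters at the start of the symbol, termed a family although shared letters can join unrelated genes. These added lists were adjusted together within a comparison. WAG2, AT4G20830, MSRB9, AT5G47980, AT5G19110, PUB22, PUB23, PUB25, PUB26, UGT72E2, UGT85A2, UGT76D1, psbZ and psaC, and GH3.1, IAA30 and HAT2 in the comparison of IPyA with L-AOPP, were chosen after their values were seen wherever the rule did not name them.

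The fits were tested on simulated data with 15922 probe sets in each of 5 runs, of which 200 were changed in the comparison of L-AOPP with mock. The spread was that of the paired fit over all arrays, and effects of the replicate number were put into the data. A gain from pairing was therefore built in, and its size here does not measure the gain on the real arrays. Without pairing, 10.1% of 1.5-fold changes, 59.1% of 2-fold changes and 92.7% of 4-fold changes were called, with 1 false call among 539. With pairing these shares were 62.4%, 92.2% and 100%, with 70 false calls among 918 (7.63%), and a contrast without change gave 0 calls without pairing and 1 with it. Overlaps and correlations between comparisons that share arrays are given beside 20 simulations of unchanged groups. The alternatives were quantile normalization, median centring, no filter, a filter at the 50th percentile, a pseudocount of 23.2, no intensity trend, array quality weights, the replicate block, a fit of only the 2 groups compared, a minimum log2 fold change of 1, each array left out in turn, and for the lists the estimated correlation, all probe sets of a member, and fry (limma), which tests whether the genes of a list move one way on balance and does not compare them with other genes.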

Results

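Transcript levels were measured on 12 arrays, 3 for each of 4 treatments: mock, L-AOPP, L-AOPP with IAA and L-AOPP with IPyA. The median signal of an array lay between 169 and 185, and the Spearman correlation between any pair of arrays lay between 0.969 and 0.988. The ratio of the 3' to the 5' probe set of the GAPDH control, a sign of RNA integrity, ranged from 1.12 to 1.51. It averaged 1.17 ± 0.0486 (SD, n = 4) in replicate 3 and 1.36 ± 0.0749 and 1.38 ± 0.106 in replicates 1 and 2. The same ratio was higher for the actin control, at 7.77 to 14.5, and for the ubiquitin control, at 2.02 to 2.70. Replicate 3 did not stand apart on these. The actin ratio averaged 10.5, 12.9 and 12.3 in replicates 1, 2 and 3, and the ubiquitin ratio 2.45, 2.14 and 2.11. Arrays with the same replicate number deviated together, so pairing by that number matters for what can be detected, as the plot of called probe sets shows.

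**Figure D1:**
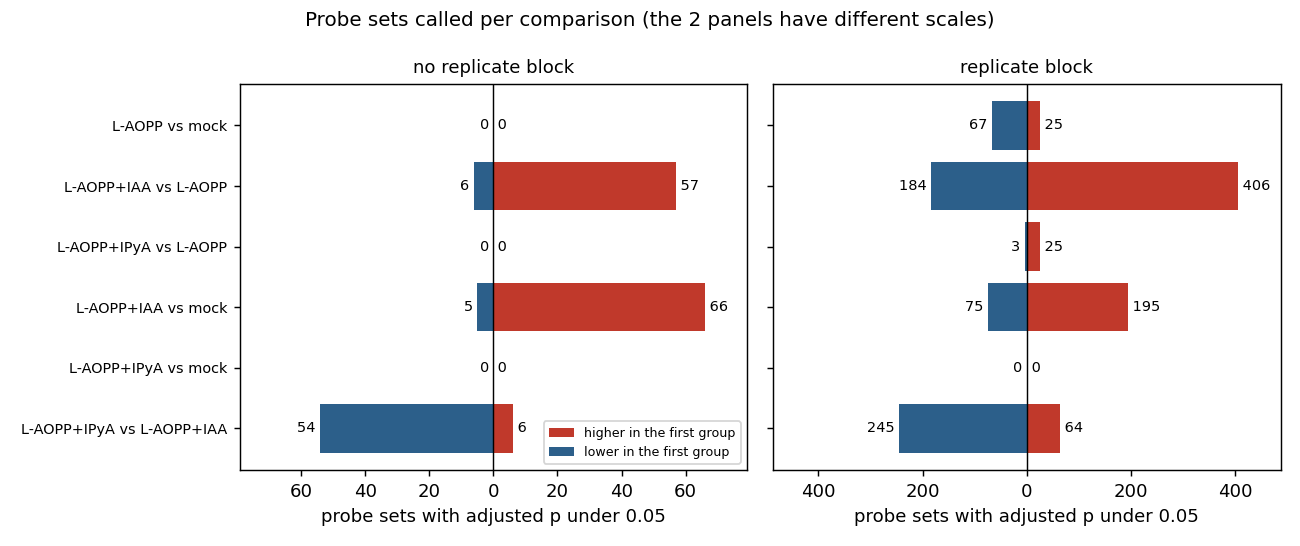
Probe sets called higher (red, to the right) or lower (blue, to the left) in the group named before the other in each comparison, at an adjusted p under 0.05, from limma without pairing (left panel) and with the replicate number as a block (right panel); the horizontal axes count probe sets and have different scales. With pairing, L-AOPP against mock has 92 calls and IAA against L-AOPP has 590, against 0 and 63 without it.

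The comparison of L-AOPP with mock asks which transcripts changed within 3 h of the inhibitor. In the paired fit, AT2G44370 was called lower with L-AOPP (adjusted p = 0.00056). Its log2 change was -1.42 ± 0.18 (SE of the fit without pairing), 2.67-fold, from a signal of 264 ± 23.5 in mock (SD, n = 3) to a mean of 99.7. AT5G47980, a BAHD acyltransferase gene of the thalianol cluster, fell from 347 ± 29.3 to 152.5 ± 10.8 (2.27-fold, adjusted p = 0.00377), and AT5G19110 fell from 479.5 ± 43.8 to 211 ± 42.2 (2.30-fold, adjusted p = 0.00637). MSRB9, a methionine sulfoxide reductase gene, fell 1.93-fold from 5291 ± 1350 to 2713 ± 447 (adjusted p = 0.000344), and AT4G20830, which encodes a berberine bridge enzyme-like oxidase, fell 1.89-fold (adjusted p = 0.00324). The defensin gene PDF2.5 rose 2.01-fold, from 476 ± 10.7 to 964 ± 116 (adjusted p = 0.0179). AT5G62340 rose by 1.00 on the log2 scale (adjusted p = 0.0232) and WAG2, a kinase gene of the group that phosphorylates PIN auxin carriers, by 0.88 (adjusted p = 0.0493). Each of these genes moved the same way in 3 of 3 pairs, as all 92 called probe sets did. The naming rule requires a shared direction of the largest changes, and a call from 3 pairs nearly does. Here and below it is therefore no separate support. None of the 92 was called without pairing, where AT2G44370 came nearest (adjusted p = 0.0985).

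The paired fit also called smaller rises of AT3G13650 (0.77), AT1G73620 (0.68), AT5G66590 (0.64), AT5G65650 (0.54), AT4G28310 (0.53), AT3G13230 (0.50) and AT3G04920 (0.41). Further falls were those of AT2G24600 (-1.38), AT4G28085 (-0.95, or -0.56 without mock replicate 2) and the transporter gene AT1G72140 (-0.91). Plastid-encoded photosynthesis genes were among the falls: petG (-0.97, adjusted p = 0.0289) and petL (-0.81, adjusted p = 0.00703) of the cytochrome b6f complex, psaC (-0.63, adjusted p = 0.00637) of photosystem I and psbZ (-0.57, adjusted p = 0.00637) of photosystem II. The GAPDH 3'/5' ratio was also lower with L-AOPP (1.25 ± 0.0998) than in mock (1.32 ± 0.0848) in 3 of 3 pairs. The actin ratio (11.4 ± 3.13 with L-AOPP, 11.7 ± 1.51 in mock) and the ubiquitin ratio (2.18 ± 0.132, 2.17 ± 0.102) differed by less than their spread.

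Of the early auxin genes, GH3.3, WES1, IAA29 and LBD16 were not called with L-AOPP in either fit. GH3.3, an IAA-amido synthetase gene that auxin induces, stood at 859 ± 351 with L-AOPP and 550.2 ± 263 in mock, a log2 difference of 0.69 (95% interval -0.29 to 1.67). The related GH3.5 gene, WES1, differed by 0.39 (-0.23 to 1.00), IAA29, an Aux/IAA repressor gene, by 0.19 (-0.61 to 0.98), and LBD16, a regulator of lateral root initiation, by 0.18 (-0.21 to 0.58). IAA29 was dim in both groups (38.7 and 44.4, under the filter level of 47.4), so its value cannot show whether L-AOPP lowered it. The differences are loose: GH3.3 was 0.31 without mock replicate 3, 0.37 without L-AOPP replicate 1 and 1.04 without mock replicate 1. WES1 was 0.12 without L-AOPP replicate 1, 0.21 without mock replicate 3 and 0.65 without L-AOPP replicate 3, and LBD16 was 0.05 and 0.35 without L-AOPP replicates 3 and 2. IAA29 turned to -0.07 without L-AOPP replicate 2 and was 0.43 without mock replicate 2. All 5 tested GH3 genes lay above 0 with a median of 0.35 and 0 called; their list test gave an adjusted p of 0.0707, or 0.0168 in the paired fit, and 0.149 in the paired fit with an estimated correlation (0.112 with paired fry). The list passed without pairing when mock replicate 2 (adjusted p = 0.00603) or L-AOPP replicate 3 (0.00277) was left out. Its median was 0.16 without mock replicate 1, 0.18 without mock replicate 3, and 0.15, 0.11 and 0.59 without L-AOPP replicates 1, 2 and 3. The other early auxin genes (median 0.18, adjusted p = 0.0707) passed without L-AOPP replicate 2 (0.0412) and had a median of 0.09 without L-AOPP replicate 3. The flavonoid genes (median 0.07, adjusted p = 0.514) passed without L-AOPP replicate 3 (0.0112), where the median was 0.29. It was -0.10 without L-AOPP replicate 1, and 0.12 and 0.02 without mock replicates 2 and 3.

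Detoxification genes were lower with L-AOPP as a list (median -0.49, 0 of 5 above 0, adjusted p = 0.000859; adjusted p = 0.0876 with an estimated correlation; 0.0587 with fry). None of the 5 was called, and 0 passed adjusted over the list alone; in the paired fit GSTU25 (-0.70), UGT73B4 (-0.80) and UGT73B5 (-0.49) passed adjusted over the list alone. Cell wall loosening genes had a median of 0.02 (adjusted p = 0.514; the median was -0.03 without L-AOPP replicate 2), with EXPA15 (0.49) passing adjusted over the list alone. Over all probe sets, limma without pairing called 0 of 15922, with 528 (3.32%) at an unadjusted p under 0.05. Groups did not overlap for 1233 (7.74%), where chance gives 10% for unpaired arrays. These arrays were taken as paired, and the share that pairs give without change was not worked out. The 10% here and below is therefore no measure of chance for these arrays. The paired fit called 92, 25 higher and 67 lower, of which 24 changed at least 2-fold, and 52 have 1 gene. Without replicate 1 the paired fit called 329, without replicate 2 it called 0 and without replicate 3 it called 6, so the paired list rests on which pairs are used. It called 2 with no intensity trend and 48 with no filter.

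**Figure D2:**
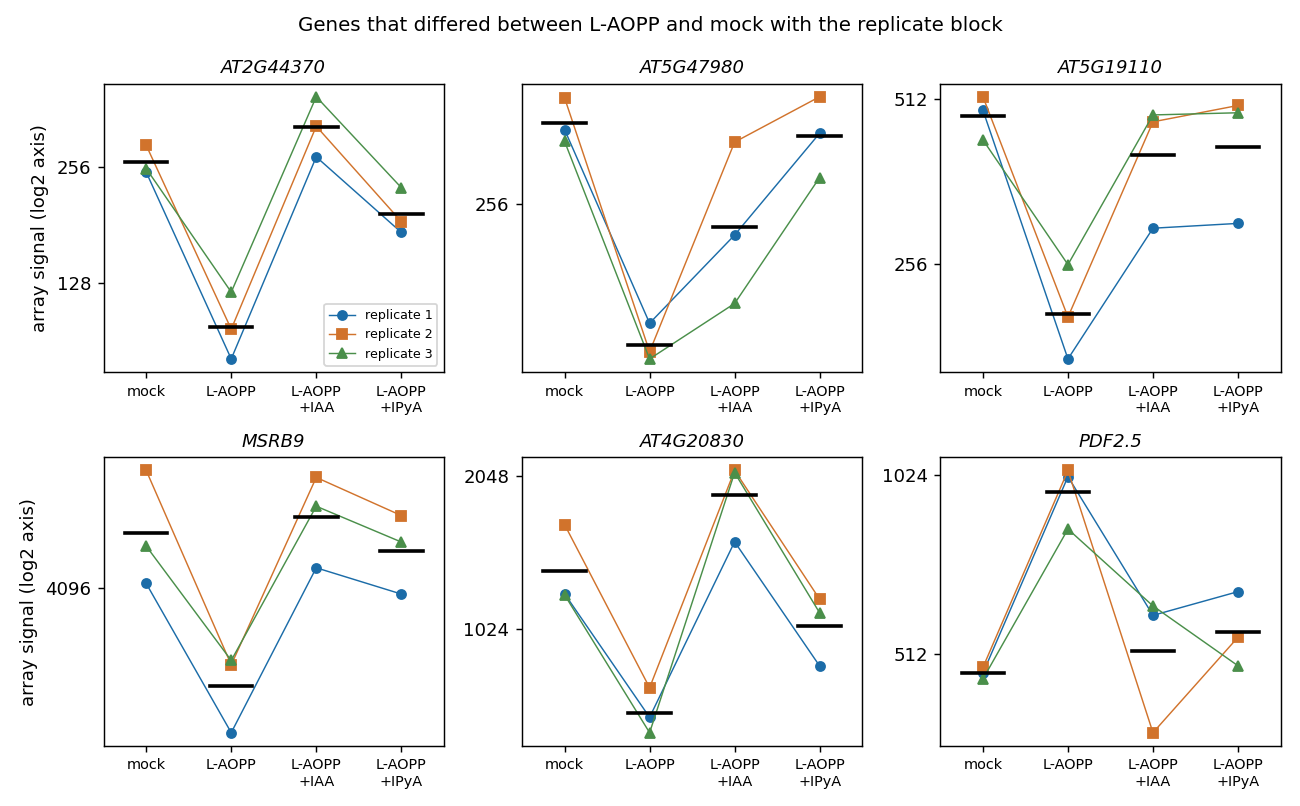
Array signal (log2 axis) of 6 genes called in the paired fit of L-AOPP against mock, by treatment; points are replicates 1 to 3, joined by lines, and black bars are group means of the log2 signal. AT2G44370, AT5G47980, AT5G19110, MSRB9 and AT4G20830 are lowest with L-AOPP alone, and PDF2.5 averages 964 there against 476 in mock.

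Adding IAA to L-AOPP-treated plants asks what auxin does to the inhibited profile. IAA raised classical early auxin genes within 2 h. GH3.3 rose 11.9-fold (3.58 ± 0.45) from a signal of 859 ± 351 to 9781 ± 882 (adjusted p = 0.00364), and HAT2, a homeobox-leucine zipper gene, rose 4.99-fold (2.32 ± 0.12) from 447 ± 16.3 to 2239 ± 200 (adjusted p = 3.95e-06). The Aux/IAA repressor gene IAA30 rose 6.76-fold to 322 ± 38.7 (adjusted p = 0.000552), IAA29 rose to 236 ± 30.1 (adjusted p = 0.0135), and LBD16 rose 3.39-fold to 831 ± 95.5 (adjusted p = 0.000984). GH3.1 rose 10.2-fold to 920 ± 208 (adjusted p = 0.0313) and WES1 3.14-fold to 5832 ± 562 (adjusted p = 0.0313). AT5G60350 (2.25, adjusted p = 0.0165), AT3G09280 (2.15, adjusted p = 0.000984) and AT4G20830 (1.42, adjusted p = 0.00348) rose as well, as did AT2G44370, by 1.72 ± 0.18 to 329 ± 58.7 (adjusted p = 0.00136). IAA29 and AT3G09280 lay below the filter level of 47.4 with L-AOPP alone, so the size of their rises is uncertain. All rises named here held in 3 of 3 pairs, as did all called changes. When an array was left out, the calls of GH3.3, IAA30, HAT2, LBD16, AT3G09280, AT2G44370 and AT4G20830 held each time. The call of GH3.1 ended without any of the 6 arrays (adjusted p 0.0559 to 0.154) and that of WES1 without any but L-AOPP replicate 1 (0.093 to 0.126). That of AT5G60350 ended without any but L-AOPP+IAA replicate 3 (0.0509 to 0.0927) and that of IAA29 without replicate 1 or 3 of L-AOPP or replicate 1 or 2 of L-AOPP+IAA (0.0617 to 0.0819).

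Fewer genes fell with IAA. UPB1, a transcription factor gene that controls peroxidase expression in the root, fell 2.23-fold, from 230.0 ± 43.7 to 103 ± 18.4 (-1.16 ± 0.21, adjusted p = 0.0439). AT2G43880 fell 2.85-fold (-1.51 ± 0.26, adjusted p = 0.0313), AT3G52480 by 0.95 (adjusted p = 0.0313) and AT1G72200 by 0.86 (adjusted p = 0.0302), each in 3 of 3 pairs. UPB1 and AT1G72200 lost the call without any of the 6 arrays (adjusted p 0.0572 to 0.212 and 0.0506 to 0.147), AT3G52480 without any but L-AOPP+IAA replicate 2 (0.114 to 0.139) and AT2G43880 without any but L-AOPP+IAA replicate 1 (0.107 to 0.159). All 4 ended in a fit of only the 2 groups (adjusted p 0.0838 for AT1G72200, 0.0795 for AT3G52480, 0.0972 for UPB1 and 0.117 for AT2G43880). The UPB1 call also ended with quantile normalization (0.0518), median centring and no filter (0.068).

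By list, 3 of 5 tested GH3 genes rose over all probe sets, as 3 did adjusted over the list alone (adjusted p = 5.14e-07; adjusted p = 0.0218 with an estimated correlation), while GH3.17 (-0.06) and GH3.9 (0.01) stayed near 0. Of the 5 other early auxin genes, 2 rose, HAT2 and LBD16, and 2 passed adjusted over the list alone (median 0.73, or 0.46 without L-AOPP replicate 3; adjusted p = 7.22e-08; 0.00206 with an estimated correlation). Of the 4 tested Aux/IAA genes, IAA29 and IAA30 rose and 2 passed adjusted over the list alone; IAA18 (0.30) and IAA20 (0.33) were not called. Detoxification genes rose as a list (median 0.91, adjusted p = 4.07e-06; 0.0142 with an estimated correlation) with 0 called and 3 passing adjusted over the list alone. The paired fit called UGT73B4 (1.35), GSTU25 (1.08) and UGT73B5 (0.91). Cell wall loosening genes rose as a list (median 0.29, or 0.11 without L-AOPP replicate 3; adjusted p = 0.0106; 0.0326 with an estimated correlation). XTH19, a xyloglucan endotransglucosylase gene, rose by 0.66 ± 0.11 (adjusted p = 0.0231), and 3 passed adjusted over the list alone. The paired fit added XTH18 (1.01) and the expansin gene EXPA8 (0.43) as higher and EXPA15 (-0.45) as lower. The change of EXPA8 is poorly fixed, at 0.10 without L-AOPP replicate 3, 0.65 without L-AOPP replicate 2 and 0.67 without L-AOPP+IAA replicate 3. The call of XTH19 ended without any array but L-AOPP+IAA replicate 3 (adjusted p 0.0559 to 0.114) and in a fit of only the 2 groups (0.122). The flavonoid list (median 0.18) was called only in the paired fit (adjusted p = 0.152 without pairing, 0.0449 with it, 0.375 with pairing and an estimated correlation, 0.328 with paired fry); without pairing it passed when L-AOPP replicate 1 (0.0011) or L-AOPP+IAA replicate 3 (0.00921) was left out, where its median was 0.36 and 0.37. The median was -0.08 without L-AOPP replicate 3, and 0.02 and 0.07 without L-AOPP+IAA replicates 1 and 2.

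In all, IAA called 63 probe sets, 57 higher and 6 lower, 53 of them at least 2-fold, and 31 have 1 gene. Groups did not overlap for 1619 probe sets (10.2%), called or not, where chance gives 10% for unpaired arrays. Leaving out replicate 1, 2 or 3 of L-AOPP left 30, 32 or 23 calls, and leaving out replicate 1, 2 or 3 of L-AOPP+IAA left 24, 27 or 37. The paired fit called 590 (406 higher, 184 lower), which include all 63, and 119 without replicate 2, 193 without replicate 3 and 353 with no intensity trend. Its further rises were led by AT5G52750 (2.25, adjusted p = 0.000927), AT2G32020 (2.13, adjusted p = 0.000979), AT2G41730 (2.08, adjusted p = 0.00316), MSRB9 (1.05, adjusted p = 9.35e-06) and AT5G19110 (0.96, adjusted p = 0.00358), and AT5G47980 (0.63, or 0.40 without L-AOPP+IAA replicate 2; adjusted p = 0.0245) and WAG2 (0.71, adjusted p = 0.0431) rose too. Its further falls included AT1G36060 (-2.21, adjusted p = 0.0204), AT3G24210 (-1.46), AT3G59850 (-1.45), AT3G01730 (-1.39), AT1G19900 (-1.37), the cytochrome P450 gene CYP718 (-1.32), the beta-glucosidase gene BGLU28 (-1.30), AT3G11370 (-1.28) and AT1G44050 (-1.27). Signals under the filter level, of AT5G52750 with L-AOPP (38.5) and of AT1G36060 (28.8) and AT3G11370 (36.2) with IAA, leave the size of those changes uncertain. Without pairing, AT1G36060 was called when L-AOPP+IAA replicate 2 was left out (-2.98, adjusted p = 0.00268) and AT3G59850 when L-AOPP+IAA replicate 3 was left out (0.0216). PDF2.5, higher with L-AOPP, was lower after IAA (-0.89, adjusted p = 0.00658).

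Adding IPyA to L-AOPP-treated plants asks whether the precursor acts as IAA does; the dose was 100 µM or 0.1 µM, depending on the label read. In the paired fit, some genes called lower with L-AOPP than in mock were called higher with IPyA than with L-AOPP. Both comparisons use the same L-AOPP arrays, so part of such a rise can be chance. Probe sets picked as lower in simulated unchanged groups rose by a median of 0.20. AT5G47980 rose 2.17-fold (1.11 ± 0.20), from 152.5 ± 10.8 to 332 ± 49.3 (adjusted p = 0.00659), AT5G19110 2.01-fold to 429 ± 109 (adjusted p = 0.025), AT2G44370 1.96-fold to 194 ± 27.9 (adjusted p = 0.00944) and MSRB9 1.79-fold to 4859 ± 810.3 (adjusted p = 0.00139), each in 3 of 3 pairs. The transporter genes AT3G45680 (0.92, or 0.57 without L-AOPP+IPyA replicate 1; adjusted p = 0.0449) and AT1G72140 (0.90, adjusted p = 0.0417), the mitochondrial gene ccb382 of cytochrome c biogenesis (0.78, adjusted p = 0.0417), AT3G46280 (0.63, adjusted p = 0.0132), psbZ (0.55, adjusted p = 0.0103) and psaC (0.55, adjusted p = 0.0227) rose as well. Without pairing none was called.

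GH3.3, GH3.1, WES1, IAA29, IAA30, HAT2 and LBD16, which IAA raised, were not called with IPyA in either fit. HAT2 differed from L-AOPP alone by 0.00 (95% interval -0.26 to 0.26), LBD16 by 0.05 (-0.34 to 0.44), WES1 by -0.09 (-0.71 to 0.53), IAA30 by -0.23 (-0.79 to 0.33), GH3.3 by -0.26 (-1.24 to 0.72), GH3.1 by 0.23 ± 0.58 (SE) and IAA29 by -0.51 (-1.30 to 0.29). IAA29 was dim with L-AOPP (44.4) and with IPyA (32.7), as was IAA30 with IPyA (41.3), against the filter level of 47.4, so these values cannot show a change or its absence. The others move with single arrays. GH3.3 was -0.79 without L-AOPP+IPyA replicate 1 and turned to 0.07 without replicate 3 and 0.05 without L-AOPP replicate 1. WES1 was -0.36 without L-AOPP replicate 3 and turned to 0.17 without L-AOPP replicate 1 or L-AOPP+IPyA replicate 3. LBD16 turned to -0.12 without L-AOPP replicate 2 and -0.10 without L-AOPP+IPyA replicate 1, and GH3.1 to -0.06 without L-AOPP+IPyA replicate 2 and -0.01 without L-AOPP replicate 3, with 0.59 without L-AOPP replicate 2. HAT2 stayed between -0.06 and 0.08. No list was called: the adjusted p was 0.0582 for detoxification (median 0.34), 0.151 for flavonoids (0.22), and 0.908 for the GH3 genes (-0.03), the other early auxin genes (-0.01) and cell wall loosening (-0.02), with 0 members called and 0 passing adjusted over the list alone in each. Detoxification passed with quantile normalization (adjusted p = 0.0341) and median centring (0.0358), and flavonoids passed without L-AOPP replicate 1 (0.00017). The flavonoid median was 0.41 there, -0.08 without L-AOPP replicate 3, and 0.05 and 0.34 without L-AOPP+IPyA replicates 1 and 3. The GH3 median turned positive without L-AOPP replicate 1 (0.12) or 2 (0.06) or L-AOPP+IPyA replicate 3 (0.17), that of the other early auxin genes without L-AOPP replicate 1 (0.0063), and that of cell wall loosening without L-AOPP replicate 1 (0.06) or 2 (0.04) or L-AOPP+IPyA replicate 2 (0.0074) or 3 (0.0019). Over all probe sets, limma without pairing called 0, with 367 (2.30%) at an unadjusted p under 0.05. For 957 (6.01%) the groups did not overlap, where chance gives 10% for unpaired arrays. The paired fit called 28, 25 higher and 3 lower; it called 75 without replicate 1, 0 without replicate 2 and 3 without replicate 3. With no filter it called 11 and with no intensity trend 0.

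**Figure D3:**
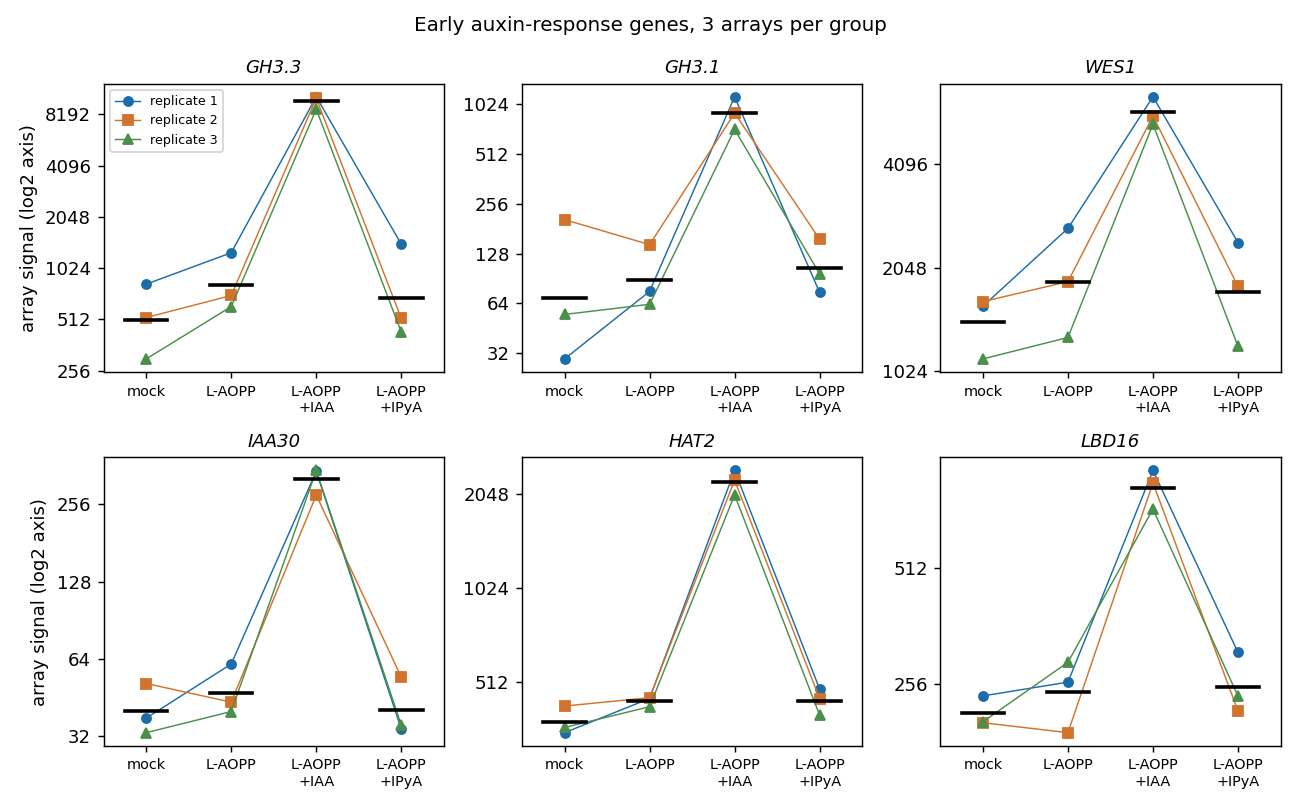
Array signal (log2 axis) of 6 early auxin genes by treatment; points are replicates 1 to 3, joined by lines, and black bars are group means of the log2 signal. GH3.3 averages 9781 with L-AOPP and IAA, and 550.2, 859 and 789 in mock, L-AOPP and L-AOPP with IPyA.

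IAA and IPyA were compared directly, at doses that differ from each other (1 µM IAA, and 100 µM or 0.1 µM IPyA) and after the same 2 h. Early auxin genes were lower with IPyA than with IAA. GH3.3 was 14.3-fold lower (-3.84, 95% interval -4.82 to -2.86; 789 ± 544 against 9781 ± 882; adjusted p = 0.00211), HAT2 4.99-fold lower (-2.32, -2.58 to -2.06; adjusted p = 3.95e-06) and LBD16 3.28-fold lower (-1.71, -2.11 to -1.32; adjusted p = 0.00133). IAA30 (-2.99, -3.55 to -2.43; adjusted p = 0.000232) and IAA29 (-2.96, -3.76 to -2.17; adjusted p = 0.00299) were lower too, but their signals with IPyA (41.3 and 32.7) lie below the filter level of 47.4, so the size of these differences is uncertain. GH3.1 was 8.70-fold lower (adjusted p = 0.0479), WES1 3.34-fold lower (adjusted p = 0.021), and the glycosyltransferase gene UGT76D1 lower by -1.51 (adjusted p = 0.00899). Higher with IPyA were AT3G21680 (1.25, adjusted p = 0.0327), AT4G01140 (1.23, adjusted p = 0.0279), AT3G49930 (1.06, adjusted p = 0.0298) and AT5G24100 (0.99, adjusted p = 0.0388). Each difference had the same sign in 3 of 3 pairs, as did all called differences. The calls of GH3.3, HAT2, IAA29, IAA30 and LBD16 held without any 1 array. Those of GH3.1 and AT3G49930 ended without any of the 6 arrays (adjusted p 0.0825 to 0.225 and 0.0696 to 0.158), and those of WES1 and AT3G21680 without any but L-AOPP+IPyA replicate 1 (0.0627 to 0.113 and 0.0815 to 0.187). AT4G01140 lost its call without any but L-AOPP+IAA replicate 2 (0.0997 to 0.139), AT5G24100 without replicates 1 or 2 of either group (0.164 to 0.188) and UGT76D1 without L-AOPP+IAA replicate 1 or L-AOPP+IPyA replicate 3 (0.0544 to 0.0653).

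Some genes that L-AOPP changed were not called between IAA and IPyA and others were. The difference was 0.05 for AT5G19110 (95% interval -0.46 to 0.56), 0.10 for AT1G72140 (-0.43 to 0.63), -0.21 for MSRB9 (-0.66 to 0.25) and 0.49 for AT5G47980 (0.06 to 0.91; adjusted p = 0.931, or 0.133 paired), and for PDF2.5 it was 0.11 (-0.29 to 0.51). AT4G20830 (-0.85, adjusted p = 0.000584), AT2G44370 (-0.75, adjusted p = 0.00737) and WAG2 (-0.81, adjusted p = 0.0351) were lower with IPyA in the paired fit. That fit also placed XTH19 (-0.47, adjusted p = 0.0039) and XTH18 (-0.74, or -0.48 without L-AOPP+IPyA replicate 1; adjusted p = 0.0391) lower and AT4G25250 (1.45, adjusted p = 0.0183), AT3G11370 (1.27), AT3G24210 (1.26) and AT2G43880 (1.25, adjusted p = 0.00675) higher with IPyA, AT3G11370 from a dim 36.2 with IAA; without pairing AT2G43880 was called when L-AOPP+IAA replicate 1 was left out (0.0261). Of the 67 probe sets lower with L-AOPP in the paired fit, 11 were called lower and 1 higher with IPyA than with IAA. Of the 25 higher probe sets, 4 were called lower and 0 higher.

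As lists, the GH3 genes (3 of 5 lower, 3 adjusted over the list alone; adjusted p = 2.36e-08, 0.0133 with an estimated correlation), the other early auxin genes (2 of 5 lower, 2 adjusted over the list alone; 8.62e-11, 0.000645 with an estimated correlation), detoxification (median -0.54, or -0.31 without L-AOPP+IAA replicate 2; 0 called, 0 adjusted over the list alone; 0.000491, 0.0259 with an estimated correlation) and cell wall loosening (0 called, 1 adjusted over the list alone; 0.00061, 0.0133 with an estimated correlation) were lower with IPyA. Flavonoids were not called (0.909). Of the Aux/IAA genes 2 of 4 were lower, and 4 passed adjusted over the list alone. In total 60 probe sets were called, 6 higher and 54 lower with IPyA, 26 of them with 1 gene and 52 at least 2-fold. For 1149 (7.22%) the groups did not overlap, where chance gives 10% for unpaired arrays. The count was 25 or 32 without replicate 1 or 2 of L-AOPP+IAA, and 37 or 29 without replicate 1 or 3 of L-AOPP+IPyA. The paired fit called 309 (64 higher, 245 lower), and 118 without replicate 2 or without replicate 3.

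L-AOPP with IAA was set against mock to show which genes auxin moved beyond the untreated level. GH3.3 was 19.2-fold higher (4.27 ± 0.45, adjusted p = 0.000793), IAA30 by 3.00 ± 0.26 on the log2 scale (adjusted p = 0.000203), HAT2 5.83-fold (2.54 ± 0.12, adjusted p = 1.38e-06) and LBD16 3.85-fold (1.94 ± 0.18, adjusted p = 0.000327). GH3.1 (3.71 on the log2 scale, adjusted p = 0.0141), IAA29 (2.64 on the log2 scale, adjusted p = 0.00619), WES1 (2.04 on the log2 scale, adjusted p = 0.00642), WAG2 (3.02-fold, 569.8 ± 20.2 against 194 ± 54.7, adjusted p = 0.00543) and UGT76D1 (3.00-fold, adjusted p = 0.006) were higher too. AT4G01140 (-1.26, adjusted p = 0.0205), AT5G24100 (-1.06, adjusted p = 0.0228) and AT4G20460 (-0.63, adjusted p = 0.0393) were lower. Each moved the same way in 3 of 3 pairs, as did all called probe sets. IAA30 and IAA29 were dim in mock (40.7 and 38.7), so the size of their rises is uncertain. So is that of GH3.1, whose mock signal was 96.5 ± 94.98 and whose change was 3.09 and 4.49 without mock replicates 1 and 2. The calls of GH3.3, IAA30, HAT2, LBD16, WAG2 and UGT76D1 held without any 1 array. GH3.1 lost its call without mock replicate 3 or L-AOPP+IAA replicate 1 or 2 (adjusted p 0.0658 to 0.0929), AT4G01140 without mock replicate 1 or 2 or L-AOPP+IAA replicate 1 or 3 (0.0624 to 0.109), AT5G24100 without any but L-AOPP+IAA replicate 3 (0.0547 to 0.125), and AT4G20460 without any of the 6 (0.0898 to 0.195). IAA29 and WES1 came to lie just over the threshold without L-AOPP+IAA replicate 1. In a fit of only the 2 groups the calls of GH3.1 (0.110) and UGT76D1 (0.0758) ended too.

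Here 3 of 5 GH3 genes (adjusted p = 9.26e-11; 0.00617 with an estimated correlation) and 2 of 5 other early auxin genes (3.16e-11; 0.000556 with an estimated correlation) were higher, with 3 of each adjusted over the list alone. The added gene is PUCHI (1.14, from a dim 39.5 in mock), a regulator of lateral root primordia. Cell wall loosening genes were higher as a list (median 0.33, adjusted p = 0.000106; 0.00617 with an estimated correlation) with 0 called and 1 adjusted over the list alone; the paired fit called EXPA4 (0.54) and XTH19 (0.48). The flavonoid list (median 0.24, adjusted p = 0.0309; adjusted p = 0.316 with an estimated correlation; 0.377 with fry) and the detoxification list (median 0.38, adjusted p = 0.0309; adjusted p = 0.146 with an estimated correlation; 0.175 with fry) were higher with 0 called and 0 adjusted over the list alone. Flavonoids lost the call without mock replicate 1 or 3 or L-AOPP+IAA replicate 1 or 2 (0.0805 to 0.350); their median was 0.08 without L-AOPP+IAA replicate 1 and 0.42 without replicate 3. Detoxification lost it without mock replicate 1 or 3 or L-AOPP+IAA replicate 2 or 3 (0.124 to 0.186), and its median was 0.22 without mock replicate 3 or L-AOPP+IAA replicate 2 and 0.64 without mock replicate 2. Of the Aux/IAA genes 2 of 4 were higher and 3 passed adjusted over the list alone; the paired fit added IAA18 (0.43, adjusted p = 0.0441). It also raised AT4G35200 (adjusted p = 0.0212), from a dim 26.9 ± 22.2 in mock to 220.3 ± 86.8, a change whose log2 value moved from 3.99 to 2.41 without mock replicate 1 and to 4.84 without mock replicate 2, rose without mock replicate 3 too and is not well measured, and lowered AT1G36060 (-2.11), AT1G56660 (-1.39), AT3G11370 (-1.26) and AT1G69080 (-1.26). The size of the falls of AT1G36060, AT1G56660 and AT3G11370 is uncertain too, as their signals with IAA (28.8, 44.7 and 36.2) lie under the filter level. Without pairing, AT4G35200 was called when mock replicate 1 was left out (0.038) and AT1G36060 when L-AOPP+IAA replicate 2 was left out (-2.87, adjusted p = 0.00219). In total 71 probe sets were called, 66 higher and 5 lower, 31 of them with 1 gene and 59 at least 2-fold. Another count, of probe sets that did not overlap between groups, was 1195 (7.51%), where chance gives 10% for unpaired arrays. The count was 40 without mock replicate 3, 30 without L-AOPP+IAA replicate 1, 46 without L-AOPP+IAA replicate 2 and 38 in a fit of only the 2 groups. The paired fit called 270 (195 higher, 75 lower), and from 121 (without replicate 3) to 168 (without replicate 1) with 1 replicate number left out.

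L-AOPP with IPyA, whose dose is not settled, was set against mock to show what remained of the inhibitor's changes. No gene was called in either fit. MSRB9 (-0.11), AT5G47980 (-0.07), AT5G19110 (-0.19), AT2G44370 (-0.45) and PDF2.5 (0.23) lay nearer to mock than with L-AOPP alone, while WAG2 stood at 0.78. These genes were picked for their change with L-AOPP, and some return towards mock follows from such a pick. Probe sets picked as lower in simulated unchanged groups had a median of -0.41 with L-AOPP and -0.21 with IPyA. GH3.3 (0.43, 95% interval -0.55 to 1.41), WES1 (0.30), LBD16 (0.23) and IAA29 (-0.32) were not called. IAA29, at 38.7 in mock and 32.7 with IPyA, is too dim for a change to be read. GH3.3 turned to -0.10 without L-AOPP+IPyA replicate 1 and was 0.05 and 0.78 without mock replicates 3 and 1 and 0.76 without L-AOPP+IPyA replicate 3. WES1 was 0.06 and 0.56 without L-AOPP+IPyA replicates 1 and 3 and 0.12 without mock replicate 3, and LBD16 was 0.08 without L-AOPP+IPyA replicate 1. As lists, the GH3 genes (median 0.30, adjusted p = 0.0263; adjusted p = 0.226 with an estimated correlation; 0.365 with fry) and the flavonoid genes (median 0.26, adjusted p = 0.0154; adjusted p = 0.226 with an estimated correlation; 0.365 with fry) were higher, each with 5 of 5 above 0, 0 called and 0 adjusted over the list alone. Each lost the call without mock replicate 3 or L-AOPP+IPyA replicate 1 or 2 (0.113 to 0.364 for GH3 genes, 0.0678 to 0.219 for flavonoids). The GH3 median was 0.10 without mock replicate 3 or L-AOPP+IPyA replicate 1 and 0.56 without L-AOPP+IPyA replicate 3, and the flavonoid median was 0.12 and 0.43 without L-AOPP+IPyA replicates 1 and 3. The other early auxin genes (median 0.22, adjusted p = 0.0579) passed without mock replicate 1 (0.0421) and had a median of 0.12 without mock replicate 2 and 0.11 without L-AOPP+IPyA replicate 1. The detoxification list (median -0.16, adjusted p = 0.063) passed without mock replicate 1 or 3 (0.0421, 0.0326), with medians of -0.28 and -0.34. Its median was 0.07 without mock replicate 2, and -0.32 and -0.09 without L-AOPP+IPyA replicates 2 and 3. Both lists passed with quantile normalization (0.0479) and median centring (0.0469). Cell wall loosening was not called (0.4). Over all probe sets limma called 0 without pairing, with 150 (0.942%) at an unadjusted p under 0.05, and 0 with pairing, with 882 at an unadjusted p under 0.05. Between groups 634 (3.98%) did not overlap, where chance gives 10% for unpaired arrays.

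The L-AOPP profile and the effects of the additions were compared gene by gene. Of the 92 probe sets called by L-AOPP in the paired fit, IAA moved 51 the opposite way, 36 lower with L-AOPP and 15 higher, where independent calls would share 1.71 and 0.289. IPyA moved 22 the opposite way, 19 lower with L-AOPP and 3 higher, where independent calls would share 0.105 and 0.00471. With the difference of IPyA from IAA, L-AOPP shared 11 calls in the same direction (independent calls: 0.1 higher and 1.03 lower) and 5 in the opposite direction (0.269 and 0.385), and 0 in simulation. Among the 28 probe sets called by IPyA, 19 were called the same way by IAA (independent calls: 0.637 higher and 0.0347 lower). Simulated unchanged groups gave 0.1 on average and at most 1 in each of the other cases, and without pairing each count was 0. Groups without change have hardly any calls to share, so low simulated counts were set in advance. The expectation for independent calls leaves out the sharing of the L-AOPP arrays. Neither value therefore shows how many shared calls chance deviations of those arrays could give. The 67 probe sets lower with L-AOPP had a median of -0.79 against mock, where the same selection in simulated unchanged groups gave -0.41. Their medians were 0.50 after IAA and 0.52 after IPyA (0.21 and 0.20 simulated). That left them at -0.23 and -0.24 against mock, near the simulated -0.20 and -0.21. The simulated falls were smaller, so the larger rises do not by themselves show a reversal beyond chance. The 25 higher probe sets had a median of 0.68 against mock (0.47 simulated), -0.46 after IAA and -0.42 after IPyA (-0.22 simulated for each). That left them at 0.10 and 0.12 against mock (0.23 and 0.22 simulated).

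Across the 15922 probe sets, which are not independent replicates, the L-AOPP changes correlated with the IAA changes at Pearson's r = -0.473 (Spearman's rho = -0.492) and with the IPyA changes at r = -0.665 (rho = -0.614). Unchanged groups sharing the L-AOPP arrays gave r = -0.499 in both cases, so the covariance is the better measure: it was -0.0314 against -0.0121 simulated with IAA (difference -0.0194) and -0.0307 against -0.012 simulated with IPyA (difference -0.0186). No spread was worked out for these differences. The IAA and IPyA changes correlated with each other at r = 0.485 (rho = 0.555; 0.499 simulated), with a covariance of 0.0276 against 0.0121 simulated (difference 0.0155). That r ranged from 0.286 without L-AOPP+IPyA replicate 2 to 0.637 without L-AOPP replicate 2. Between the L-AOPP changes and the difference of IPyA from IAA, which share no array, r was 0.0133 (rho = -0.0237), ranging from -0.186 without L-AOPP+IPyA replicate 1 to 0.194 without L-AOPP+IAA replicate 1.

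Lists with 1 to 4 tested members other than the Aux/IAA genes had 0 calls over all probe sets without pairing. Adjusted over the list alone, HCT, a hydroxycinnamoyltransferase gene of lignin synthesis and the only tested phenylpropanoid gene, was lower with L-AOPP (-0.31) and higher after IAA (0.32) and IPyA (0.40), and the paired fit called it after IAA over all probe sets (adjusted p = 0.0297; the change was 0.21 without L-AOPP replicate 3). RR16, a cytokinin response regulator gene, was lower with IAA than with L-AOPP (-0.46) or mock (-0.68) and higher with IPyA than with IAA (0.55), adjusted over the list alone. YUC2, the only tested auxin synthesis gene, differed by 0.48 between L-AOPP with IPyA and mock at an unadjusted p under 0.05 and was not called over all probe sets in either fit (adjusted p = 0.868 paired). HCT, RR16 and YUC2 each stand alone in their lists, so adjusted over the list alone means an unadjusted p for them. The tested genes for tryptophan synthesis, ethylene, salicylate, abscisic acid and cold, touch and wounding, glucosinolates, the cell cycle, shoot photosynthesis, root hairs, the clock and the reference set had 0 passing adjusted over the list alone without pairing. With pairing, COR15A (-1.02), GRX480 (-1.05) and STZ (-0.51) were lower and the root hair expansin genes EXPA7 (0.72) and EXPA18 (0.67) higher with L-AOPP than in mock, adjusted over the list alone. GRX480 and STZ also stand alone in their lists, so theirs is an unadjusted p too. EXPA7 varied widely, at 836 ± 947 in mock and 982 ± 535 with L-AOPP. Over all probe sets neither EXPA7 (adjusted p = 0.178) nor EXPA18 (0.115) was called in the paired fit. In other comparisons, members of the auxin synthesis, tryptophan, salicylate, abscisic acid and cold, touch and wounding, cell cycle and root hair lists passed this way too. So did 1 of the 2 tested reference genes, between IPyA and IAA. The SAUR, auxin transport and perception, jasmonate, brassinosteroid and gibberellin synthesis and other root lists had no tested member.

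**Figure D4:**
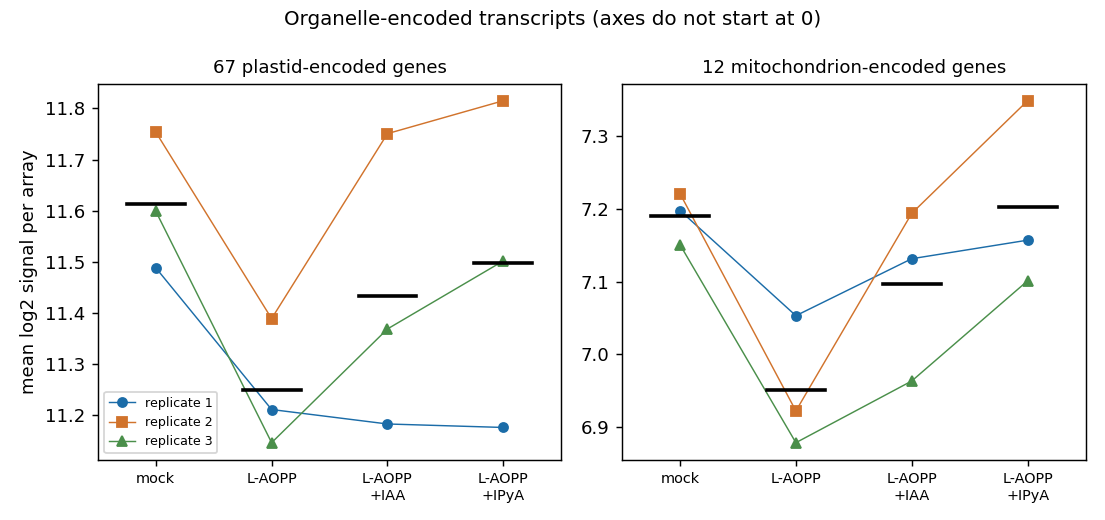
Mean log2 signal per array of 67 plastid-encoded genes and of 12 mitochondrion-encoded genes, by treatment; points are replicates 1 to 3, joined by lines, black bars are group means, and the vertical axes do not start at 0. The plastid mean is lower with L-AOPP than in mock in each of the 3 pairs, and in replicate 1 it does not rise after IAA or IPyA.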

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

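The replicate block, quality weights and scaling alternatives were planned; the paired counts under a further change, and the estimated correlation with pairing, were chosen after the data were seen. Of 129 gene results, 55 kept their side of the threshold with the replicate block and 74 gained a call. The block ended no gene call. Genes were also named from the paired calls, so these gains were in part set by the naming. Each setting is compared here with the fit without pairing. A kept result can thus be a gene that stayed uncalled, and the paired calls of single genes were not retested under these settings. Among the lists it ended the call of the GH symbols in L-AOPP with IPyA against mock (adjusted p = 0.0608), brought the list calls named with the paired fit, and changed no other call. With quantile normalization 126 of 129 gene results were kept, with no intensity trend 128, with a filter at the 50th percentile all 79 that it still tested, and in a fit of only the 2 groups 115, the other 14 losing the call, where fewer arrays estimate the spread. No named gene reversed. Quantile normalization kept 61 of the 63 probe sets called for IAA against L-AOPP, 68 of the 71 for L-AOPP with IAA against mock and 58 of the 60 for IPyA against IAA. When 1 array was left out, 656 gene results were kept, 100 lost the call, 5 gained it and 13 that were not called changed sign.

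Counts moved as follows. For L-AOPP against mock, array weights called 1 (AT2G44370) and the replicate block 92; for IPyA against L-AOPP the block called 28. For IAA against L-AOPP the 50th percentile filter, which tests fewer probe sets, called 35, the block 590, and 23 to 37 were called without 1 array. For L-AOPP with IAA against mock these were 37, 270 and 30 to 69, and the fit of only the 2 groups called 38. For IPyA against IAA they were 33, 309 and 25 to 48. With the block, L-AOPP against mock gave 48 with no filter, 2 with no intensity trend, 24 at a log2 fold change of at least 1 and 0 to 329 without a replicate number. IAA against L-AOPP gave 353 with no trend, 167 at that minimum and 119 to 627; IPyA against L-AOPP gave 11 with no filter, 0 with no trend, 7 at that minimum and 0 to 75. With the block, L-AOPP with IAA against mock gave 174 with the 50th percentile filter, 104 and 121 to 168; and IPyA against IAA gave 116 and 118 to 222. L-AOPP with IPyA against mock gave 0 in every setting. Probe sets called by L-AOPP and the opposite way by IAA numbered 1 with array weights and 51 with the block, and by IPyA 22 with the block. The correlation of the IAA and IPyA changes ranged from 0.286 to 0.637 without 1 array, and that of the L-AOPP changes with the difference of IPyA from IAA from -0.186 to 0.194. List calls fell from 16 to 5 with the 50th percentile filter, which leaves fewer members; 11 held with an estimated correlation and 11 with fry, 18 with the block, and 14 to 18 without 1 array. The plastid-encoded list in L-AOPP with IPyA against mock, median -0.09, turned to 0.052 (adjusted p = 0.611) without L-AOPP+IPyA replicate 1 and was -0.26 without replicate 2. Apart from those filters, minimum folds and smaller fits, the cause was not tested. Without any filter, which adds the dim probe sets at or below the filter level of 47.4, 55 of 63, 64 of 71 and 55 of 60 calls were kept. These are for IAA against L-AOPP, L-AOPP with IAA against mock and IPyA against IAA. Whether dim probe sets limit what can be called was not tested.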

Other observations

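The tests of other splits of the samples were chosen after the results were seen, as were the lists of organelle genes and families; the other tests had their bounds written before their results, though after the patterns were noticed.

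Joined into 1 list of 14, the early auxin genes were strongly higher after IAA (median 1.19, adjusted p = 2.55e-19; 0.00289 with an estimated correlation), with 7 called. With L-AOPP alone they lay slightly above mock (median 0.20, or 0.30 without mock replicate 2 and 0.35 without L-AOPP replicate 3; 13 of 14 above 0, 0 called, adjusted p = 0.0103; adjusted p = 0.338 with an estimated correlation; 0.426 with fry, 0.0498 paired), and the call ended without mock replicate 3 or L-AOPP replicate 1 or 2 (adjusted p 0.0837 to 0.215). After IPyA, whose dose is not settled, the list did not differ from L-AOPP (median -0.08, or 0.0098 and 0.03 without L-AOPP replicate 1 and L-AOPP+IPyA replicate 3, adjusted p = 0.670). Nor did the list differ from mock (0.17, or 0.07 to 0.22 when 1 array was left out, adjusted p = 0.162). It was lower with IPyA than with IAA (median -1.31, adjusted p = 1.30e-27; 0.000797 with an estimated correlation) and higher with IAA than in mock (median 1.54, adjusted p = 2.92e-29; 0.000643 with an estimated correlation).

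Among the families, the PUB genes, which encode U-box ubiquitin ligases, were higher after IAA as a list of 8 (median 0.61, or 0.97 without L-AOPP+IAA replicate 1; adjusted p = 0.00669; adjusted p = 0.625 with an estimated correlation; 0.432 with fry). PUB23 (1.56, or 0.96 without L-AOPP replicate 1; adjusted p = 0.0108), PUB25 (0.88, adjusted p = 0.0119) and PUB26 (0.83, adjusted p = 0.0139) were called in the paired fit. The list call ended without L-AOPP+IAA replicate 2 (adjusted p = 0.0514) or 3 (0.0606). The list was lower with IPyA than with IAA (median -0.40, adjusted p = 0.0312; adjusted p = 0.887 with an estimated correlation; 0.788 with fry), a call that ended without L-AOPP+IAA replicate 2 or 3 or L-AOPP+IPyA replicate 1 or 3 (0.117 to 0.222). Its median was -0.74 and -0.62 without L-AOPP+IAA replicate 1 and L-AOPP+IPyA replicate 2, -0.25 without L-AOPP+IAA replicate 2 or L-AOPP+IPyA replicate 1 and -0.24 without L-AOPP+IAA replicate 3. With L-AOPP the PUB list had a median of -0.46 (adjusted p = 0.248, or 0.023 paired, 0.570 paired with an estimated correlation and 0.389 with paired fry), and passed without mock replicate 1 (0.000961). That median was -0.14 without mock replicate 2 or L-AOPP replicate 1 and -0.18 without mock replicate 3. The list also passed against mock with IAA without mock replicate 2 or L-AOPP+IAA replicate 1 (0.0105 to 0.0205) and with IPyA without mock replicate 1 (0.00259). Those medians, 0.19 and -0.20, turned sign without 1 array: with IAA without mock replicate 1 (-0.0073), and with IPyA without mock replicate 2 (0.12) or 3 (0.06) or L-AOPP+IPyA replicate 1 (0.01). PUB22 fell by 0.58 in the paired fit (adjusted p = 0.0437), a change that was -0.94 without mock replicate 1, -0.37 without mock replicate 3 and -0.25 without L-AOPP replicate 1. The UGT glycosyltransferase family was not called (adjusted p = 0.931 after IAA) and held members that went both ways in the paired fit: UGT73B4, UGT73B5 and UGT76D1 (adjusted p = 0.0159) rose after IAA, and UGT72E2 (-0.74) and UGT85A2 (-0.49) fell. The symbols that begin with GH join 4 GH3 genes, WES1 not among them, with 9 GH9 genes, so that list of 13 is no true family. It was called in L-AOPP with IAA against mock (median 0.05, 2 of 13 called; adjusted p = 0.0156; 0.734 with an estimated correlation; 0.643 with fry, 0.0421 paired) and in L-AOPP with IPyA against mock (0.0437; 0.989 with an estimated correlation; 0.963 with fry), where the paired fit ended the call (0.0608). The EXPA family was called only in the paired fit of L-AOPP against mock (0.189 without pairing, 0.023 with it, 0.570 with pairing and an estimated correlation, 0.342 with paired fry). The UBP ubiquitin protease family, with 10 of 12 above 0 in L-AOPP against mock, passed only with paired fry (0.0498; 0.185 unpaired) and not with camera (0.189, or 0.261 paired). Apart from these, no family was called with camera or fry in either fit.

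Plastid-encoded transcripts were lower with L-AOPP than in mock: the mean of 67 genes differed by -0.37 ± 0.05 (SE over 3 pairs, -0.45 to -0.28), their median by -0.38 with 4 of 67 above 0 (adjusted p = 1.32e-21; adjusted p = 0.338 with an estimated correlation; 0.426 with fry, 0.0498 paired), and the paired fit called 9 lower. The scaling of the arrays is argued against as the whole cause, since the mean stayed at -0.38 with quantile normalization and -0.36 with median centring. RNA integrity is argued against as the whole cause only as far as the GAPDH 3'/5' ratio shows it. With that ratio as a covariate the mean was -0.32 ± 0.11, although the slope of that covariate was loosely estimated (0.58 ± 0.55). The actin and ubiquitin ratios were not tried as covariates. Mitochondrion-encoded genes differed too, by -0.24 ± 0.05 over 12 genes (adjusted p = 0.00302; adjusted p = 0.265 with an estimated correlation; 0.185 with fry, 0.0498 paired; 0.0651 without L-AOPP replicate 2). An effect of L-AOPP on organelle transcripts may be a candidate explanation, found and tested on the same arrays, and it stays open together with differences in RNA handling that the GAPDH ratio does not capture.

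The plastid list was higher than with L-AOPP alone after IAA (median 0.16, adjusted p = 1.82e-06; adjusted p = 0.732 with an estimated correlation; 0.597 with fry; 0.246 without L-AOPP+IAA replicate 2, where the median was 0.05) and after IPyA (median 0.26, adjusted p = 6.42e-15; adjusted p = 0.887 with an estimated correlation; 0.985 with fry). The median after IAA was 0.34 without L-AOPP+IAA replicate 1 and 0.26 without L-AOPP replicate 2, and after IPyA it was 0.43 and 0.10 without L-AOPP+IPyA replicates 1 and 2. The GAPDH 3'/5' ratio was also higher with IPyA (1.36 ± 0.209) than with L-AOPP (1.25 ± 0.0998), and the mean rise after IPyA was 0.25 ± 0.14 as deposited and 0.19 ± 0.11 with that ratio as a covariate. The list was lower than in mock with IAA (median -0.17, adjusted p = 0.000647; adjusted p = 0.734 with an estimated correlation; 0.737 with fry), a call that ended without mock replicate 2 or L-AOPP+IAA replicate 1 or 3 (0.159 to 0.509), with medians of -0.07, -0.05 and -0.08; it was -0.36 without L-AOPP+IAA replicate 2. Against mock with IPyA it was -0.09 (adjusted p = 0.0437; adjusted p = 0.989 with an estimated correlation; 0.963 with fry), which ended without mock replicate 2 or L-AOPP+IPyA replicate 1 or 3 (0.263 to 0.628); it was 0.00 without mock replicate 2, 0.05 and -0.26 without L-AOPP+IPyA replicates 1 and 2, and -0.17 without mock replicate 1. It did not differ between IPyA and IAA (0.08, adjusted p = 0.270), but passed in the paired fit (0.0424; 0.938 with an estimated correlation; 0.693 with paired fry) and without L-AOPP+IAA replicate 2 or L-AOPP+IPyA replicate 1 (1.02e-06, 6.65e-07), where the median was 0.25 and 0.22. That median was -0.030 and 0.041 without L-AOPP+IAA replicates 1 and 3 and -0.060 without L-AOPP+IPyA replicate 2. The mitochondrial list was higher after IPyA (median 0.24, or 0.12 without L-AOPP+IPyA replicate 2, adjusted p = 0.000779, or 0.171 with an estimated correlation and 0.336 with fry). It was not called after IAA (0.20, adjusted p = 0.173), where it passed without L-AOPP replicate 1 (0.0364). Its median after IAA ran from 0.11 to 0.30 when 1 array was left out.

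Probe sets low with L-AOPP were higher after both IAA and IPyA, 36 and 19 of the 67 being called higher in the paired fit. Chance deviations of the shared L-AOPP arrays could produce such a pattern, so the 67 lowest probe sets were picked in the arrays of 1 replicate number and measured in the others. After IPyA their medians were 0.24, 0.17 and 0.24, each above the range of random sets (at most 0.06), and after IAA they were 0.84 and 0.38 when picked in replicates 2 and 3, but -0.059 when picked in replicate 1, inside that range. The bound asked for values above the range for both additions on all 3 picks, so chance and a true reversal cannot be told apart. The values after IPyA do not exclude chance by themselves. The random sets were not picked as lowest with L-AOPP, so their range may be too narrow. The 3 picks were also measured in overlapping arrays and are not independent. The scaling of the arrays is argued against, since quantile normalization with pairing left 60 and 20 opposite calls, and a reversal of L-AOPP effects by the additions stays open as a hypothesis.

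The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. Every split but the real one mixes the treatments, so a true difference adds to its spread and lowers its calls. Low counts in the other splits therefore do not show what chance alone would give. Without pairing, the real split called 63 (IAA against L-AOPP), 71 (L-AOPP with IAA against mock) and 60 (IPyA against IAA) and no other split called any, so 1 of 10 splits gave as many; in the other 3 comparisons all 10 splits called 0. With pairing the real counts were 92, 590, 28, 270 and 309 for L-AOPP against mock, IAA against L-AOPP, IPyA against L-AOPP, L-AOPP with IAA against mock and IPyA against IAA, and the highest of the other splits gave 0, 0, 3, 1 and 0. For L-AOPP with IPyA against mock the real split called 0 and another called 17, which does not part all 3 pairs; the 3 other splits that do part them called 0 in each comparison.

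Of the control probe sets, 35 were bright enough to test and 0 were called in any comparison with limma in either fit. The largest called change belonged to a probe set unlisted in the annotation. It was higher after IAA by 5.08 against L-AOPP (adjusted p = 0.000984) and by 6.39 against mock, and a different unlisted probe set by 3.94 against mock. Another was lower with L-AOPP (-3.34, paired adjusted p = 0.0126) and higher after IAA (4.52, adjusted p = 0.0549, or 0.000229 paired).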
